A study of Mus musculus with 3 samples.

How the data were processed

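The 3 libraries were made from Ter119-negative erythroblasts of mouse fetal liver, from 6 fetuses per the labels, cultured with erythropoietin and taken on days 0, 1 and 2. Chromatin was digested with micrococcal nuclease, which cuts between nucleosomes, and single-nucleosome DNA was sequenced, per the series' design text. There is 1 library per day, and whether the days share a culture is not given in the sources used here.

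The authors deposited 1 list of nucleosome positions per library. Per the submitters' processing notes, Bowtie2 and bedtools were used, in versions not given in the sources used here, with the genome build mm10. The position caller, its settings and the total read numbers are not given in the sources used here. The summit value of each position is a smoothed coverage signal scaled by the authors, per the file headers. It lies on whole steps of 1 constant per library (0.762, 0.324 and 0.626) for 98.5%, 97.4% and 98.7% of values within 0.01 of a step, as a coverage multiplied by 1 factor would. Taking 1 step as 1 unit of coverage gives relative depths of 1, 2.36 and 1.22, so a summit value of 5 takes 7, 16 and 8 steps. This is an inference from the values. The lists also give a p-value per position for the summit and for the fuzziness, deposited by the authors, which were used in no comparison here. The fuzziness score, as deposited by the authors, describes the spread of reads around a centre, and its unit is not given. All positions are 140 bp wide and no 2 centres of a list lie closer than 100 bp. Positions were called separately in each library, so sums over regions depend on how much was called, and shares or relative values within a library were compared. Position numbers are given as counted, and ratios of them at single genes were divided by the ratio of the autosome totals of the lists unless called unscaled. Duplicated or repeated sequence can be mapped to more than 1 place, which leaves values at near-identical genes uncertain.

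Gene coordinates came from a RefSeq gene table of GRCm38.p6, which has the coordinates of mm10. It held 21523 protein-coding genes on the autosomes and chromosome X after 108 genes with coordinates below 3 Mb were left out, since these belong to unplaced or alternate sequence. The table was used without strand, sequence or exons, so several planned steps were changed. Windows around start sites became windows of 500 bp on each side of both gene ends, classes of GC share became classes of gene number in the 1 Mb around each 100 kb bin with ties kept together, and CpG classes, profiles around CTCF and GATA-TAL motifs and the split into exons and introns were not run. The gene filter, the density classes and the range of maxima from 300 to 1200 bp were set after the data were examined.

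Distances between centres were counted up to 1500 bp, smoothed with a window of 31 bp on each side, and maxima within 60 bp were taken. The spacing is the slope of a line through them. Shared positions have a centre of the other list within 20 bp, beside the mean share after shifts of 1000 bp in both directions. Profiles around gene ends used steps of 10 bp from 1000 bp outside to 1000 bp inside, divided by the mean of the outer 200 bp on each side. Relative occupancy is the summed summit values in the windows of a gene per bp, divided by the same sum over the autosomes of the library. A gene was counted as higher or lower at a change of 2 times, with at least 3 positions on each day, which is a size rule and not a test. The 14 gene lists were fixed before the data were examined. Each list is described by its median log2 change and the percentile of this median among 10000 random lists of the same size matched on mean occupancy in 10 classes. Gene length was not matched, which limits the percentiles over whole genes. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

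Genes named in the text follow a rule fixed before the data were examined. For day 0 to 2 it took the 10 largest increases and 10 largest decreases among genes whose change has the same sign in both steps. For each single step it took the 3 largest in each direction. For each list it took the 2 largest in each direction from day 0 to 2, and for some lists not all of these are printed. Predicted or unnamed gene models, chromosome Y and genes within 5 kb of one already taken were left out. Hba-a1, Hba-a2, and Csf1r, Mpeg1 and C1qa in the step from day 0 to 1, were added after their values were seen. Genes named for their values over the whole gene were also chosen outside this rule.

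Errors are the SD over 19 autosomes, the range when each chromosome is left out, or exact Clopper-Pearson 95% intervals of shares and exact conditional binomial intervals of ratios of position numbers. None of them measures the spread between cultures. Depth and listing limit all comparisons, since a gene window held a median of 7, 7 and 8 positions among the genes of the size rule.

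The scripts were tested on simulated lists. Planted spacings of 180 and 195 bp were found as 180 and 195 bp, and a planted share of 30% as 30.0%. A maximum planted 85 bp inside the gene ends was found at 95 bp, 1 step of 10 bp away, so the places of maxima are no finer than such a step. For day 0 to 2, with genes of the day 0 list changed and 80% of positions kept at random, a planted fold of 3 was recovered as at least 2 times for 95.9% of 49 genes made higher and 97.9% of 47 made lower, a fold of 4 for 100% of 48 and 50, and 1.90% of 13811 unchanged genes were counted. Of 200 random lists, 6.50% fell outside the central 95%. These simulations hold no differences between cultures or digestions. In the fold test both lists were drawn from the day 0 list, so they shared most of their positions. The lists of different days share far fewer, so the 1.90% does not estimate how many unchanged genes would be counted between days. The planted arrays had a clean repeat, so they do not test the low maxima of the real lists.

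Alternatives were other tolerances, windows and weights, leaving out positions at or below the 25% quantile of summit values, no minimum number of positions with a pseudocount of 0.1, and another scaling. Because many summit values are tied at that quantile, leaving them out removed 41.4%, 34.7% and 34.4% of the lists of days 0, 1 and 2. Added after the data were examined were whole-gene windows with at least 20 positions on each day, distances between lists, the ranges of maxima from 300 to 1200 and to 1400 bp, lists without members that their name does not describe or whose windows overlap those of another member, positions with a summit value of at least 10 or 12, and 10 density classes with ties broken by chromosome order.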

Results

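Nucleosome positions were mapped by micrococcal nuclease sequencing in erythroblasts, the nucleated precursors of red cells, grown from mouse fetal liver in medium with erythropoietin, the hormone that drives red cell formation. The cells lacked Ter119, a surface marker of later erythroid stages, when the culture was started, and chromatin was taken on culture days 0, 1 and 2. The series asks how nucleosomes change during the last steps of red cell formation. There was 1 library per day, so each value below describes that library, no test between days was made and no difference has a replicate check. The lists held 3735952 positions on day 0, 2999502 on day 1 and 4474045 on day 2, each 140 bp wide, which is 1.54, 1.23 and 1.82 positions per kb of autosome. The median summit value, the authors' smoothed coverage at the centre of a position, was 7.62, 6.80 and 6.26. The median fuzziness score, which describes how widely the reads of a position are spread, was 51.0, 54.5 and 51.0. Total read numbers are not given in the sources used here. Summit values lay on a fixed step per library, and the step sizes correspond to a depth of day 1 that was 2.36 times and of day 2 that was 1.22 times that of day 0.

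Over the genome, gene-poor regions held a larger part of the nucleosome signal on day 2 than on the earlier days. The 100 kb bins with at most 1 protein-coding gene in the surrounding 1 Mb, 5626 of 24011 bins, held 4.90% of the summed summit values on day 0, 3.78% on day 1 and 9.74% on day 2. The ratio of day 2 to day 0 was 1.99 ± 0.30 (SD over the 19 autosomes, a spread within a library and not between replicates), above 1 on all 19 autosomes and between 1.46 and 2.58. These bins held 214860, 134758 and 487869 positions, with mean summit values of 6.57, 6.16 and 5.85. The most gene-rich bins, with 22 to 72 genes in the surrounding 1 Mb, held 21.8%, 24.7% and 17.96% of the signal, and their ratio of day 2 to day 0 was 0.823 ± 0.076.

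From day 0 to day 1 the difference ran the other way, with a ratio of 0.771 ± 0.15 in the gene-poorest bins, below 1 on all but 2 of the 19 autosomes, and 1.13 ± 0.077 in the gene-richest. From day 1 to day 2 the ratios were 2.58 ± 0.41 and 0.727 ± 0.059. Among positions with a summit value of 10 or more the day 0 to 1 ratio in the gene-poorest bins was 0.877 ± 0.35, above 1 on 8 autosomes, and at 12 or more it was 1.10 ± 0.94, between 0.40 and 4.71, so the lower day 1 level is not settled there. Positions were spread most evenly on day 2, when the coefficient of variation of the position number over bins was 0.630, against 0.870 on day 0 and 1.08 on day 1. Across bins, which are not independent replicates, the Spearman correlation of the log2 change with gene density was 0.21, -0.68 and -0.59 for day 0 to 1, day 1 to 2 and day 0 to 2.

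**Figure D1:**
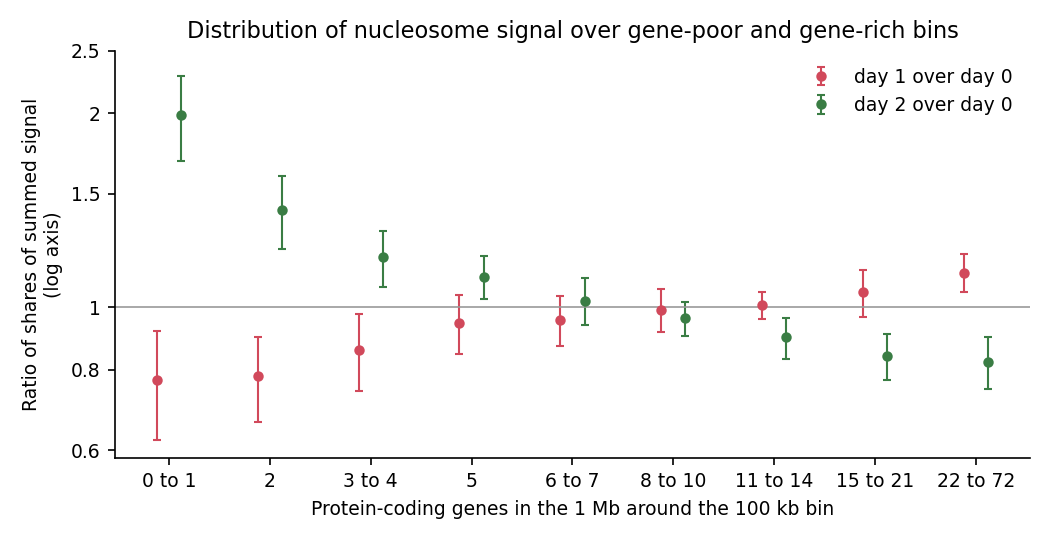
Points show the share of summed summit values in a class of 100 kb bins on day 1 (red) or day 2 (green) divided by that on day 0 (log axis), against the number of protein-coding genes in the surrounding 1 Mb, and bars show the SD over 19 autosomes. The day 2 ratio runs from 1.99 in the gene-poorest class to 0.823 in the gene-richest.

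Chromosome X had few positions in each library. Its density was 0.176 times the autosome mean on day 0, 0.149 times on day 1 and 0.289 times on day 2, and the sex of the fetuses is not given in the sources used here. Chromosome 11 stood above the mean at 1.56, 1.64 and 1.34 times, and chromosome 19 at 1.17, 1.48 and 1.28 times. Of the positions on autosomes, 44.2% lay outside protein-coding genes on day 0 (exact Clopper-Pearson 95% interval 44.2 to 44.3%), 41.7% on day 1 (41.7 to 41.8%) and 48.2% on day 2 (48.2 to 48.3%), where these regions made up 58.4% of the length. Positions within 500 bp of a gene end made up 2.87%, 3.56% and 2.67%, against 1.62% of the length. These intervals cover counting error only.

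At the ends of protein-coding genes, the summit-weighted density of positions inside the gene, relative to the outer flanks of the same library, was highest on day 1. The lists were summed around 43046 gene ends of 21523 genes, start and stop ends together since strand was not used. Just outside and across the end, from 200 bp outside to 50 bp inside, the summit-weighted density was 0.806 ± 0.030 of the outer flanks on day 0, 0.829 ± 0.027 on day 1 and 0.853 ± 0.033 on day 2 (SD over 19 autosomes). The first maximum inside the gene lay 105, 115 and 105 bp from the end, which is a difference of no more than 1 step of 10 bp, with a height of 1.28 ± 0.059, 1.53 ± 0.16 and 1.33 ± 0.086. A second maximum followed at 345, 325 and 325 bp. The ratio of the density inside to that outside was 1.16 ± 0.028 on day 0, 1.33 ± 0.044 on day 1 and 1.17 ± 0.026 on day 2. Day 1 was also the deepest library, so depth and day are not separated in this order.

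**Figure D2:**
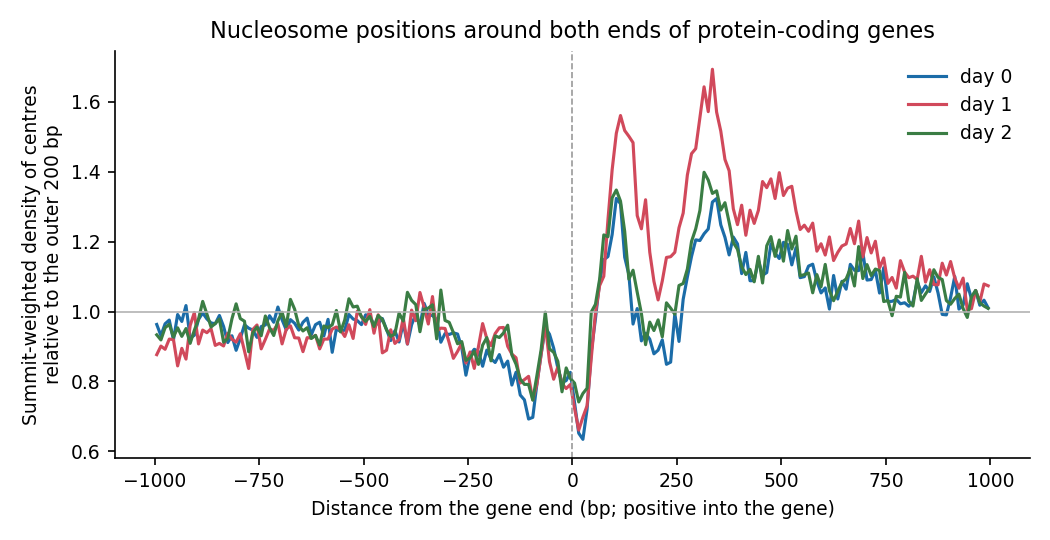
Lines show the summit-weighted density of position centres on days 0, 1 and 2, relative to the outer 200 bp on each side, against the distance in bp from the ends of protein-coding genes, positive into the gene. The first maximum inside the gene has a height of 1.28, 1.53 and 1.33.

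Single windows of 500 bp on each side of both ends of a gene were given a relative occupancy, the summed summit values per bp divided by the autosome mean of the library. Its median over all genes was 1.81 on day 0, 2.41 on day 1 and 1.79 on day 2, with means of 5.33, 5.33 and 5.90 positions per gene. Among the 14093 genes with at least 3 positions on each day, the median log2 change was 0.45 from day 0 to 1, -0.56 from day 1 to 2 and -0.11 from day 0 to 2. This last sign turned among positions with a summit value of 10 or more, where the median of 1890 genes was 0.33. Medians of lists are given below relative to these medians, and values of single genes are their log2 changes, not relative to them, unless stated.

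From day 0 to day 2 the replication-dependent histone genes stood out upward in the windows of 500 bp, though not in a narrower window given below. The median of their 48 members was 0.35 above that of all genes on the log2 scale, at percentile 99.7 of 10000 random lists matched on occupancy, and 29 members lay above the median of all genes and 19 below. H4c8 (1.30) and H2ac10 (1.25) had the largest log2 increases in the list, and H2ac1 (-1.84) and H3c6 (-1.24) the largest decreases. Histone genes are near-identical copies, so the assignment of reads among them is uncertain, and without the linker histones H1f0, H1f7, H1f8 and H1f10, which the list rule also took, the percentile was 99.2. Most of them lie in clusters on chromosomes 3 and 13, where windows of neighbours share positions, while the random lists draw scattered genes. With 37 members, kept in genome order so that no windows overlap, the median was 0.39 above all genes, at percentile 99.6, but neighbours in a cluster may still change together, which the random lists do not cover. The 96 olfactory receptor genes with enough positions, odorant receptors of the nose, lay 0.10 below all genes, at percentile 1.45, with Olfr1337 at -2.15 and Olfr543 at 1.15. Counted once per position, this percentile was 19.1, and with windows of 1000 bp 164 members lay 0.14 below all genes, lower than all 10000 random lists. Over all 1109 members the direction was the other way, with a median relative occupancy of 0.223 on day 0 and 0.473 on day 2, and 543 and 202 genes without a position, so the 96 do not stand for the list.

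In the gene-end windows the erythroid lists lay within the range of random lists from day 0 to day 2. The 16 measured erythroid transcription factors had a median equal to that of all genes to 2 decimals (percentile 60.4), with 8 above it and 8 below, but over whole genes it was 0.18 above, at percentile 99.99. Klf1, an activator of globin genes, had log2 change -1.11, Ldb1, an adaptor of the Gata1 complex, -1.03, Klf3 1.24 and Gata1, the master erythroid factor, 0.54. Klf1 lies on chromosome 8 from 84901982 to 84905291 (mm10) and had 10, 10 and 7 positions. Gata1 had 3, 3 and 5 positions. It lies on chromosome X, whose density relative to the autosome mean was 0.176 on day 0 and 0.289 on day 2. The change at Gata1 cannot be told apart from that of its chromosome. The 16 globin and heme genes lay 0.13 above all genes (percentile 71.3; -0.07 over whole genes), with Alad at 0.90, Hbb-bh1 at 0.90, Uros, a heme synthesis enzyme, at -1.05 and the transporter Abcb10 at -0.69. The adult alpha globin gene Hba-a1 had a relative occupancy of 3.47, 1.35 and 3.56 on the 3 days, and its near-identical copy Hba-a2 2.73, 2.22 and 2.31. The 17 red cell membrane genes lay 0.18 below all genes (percentile 14.3; 0.05 above in windows of 1000 bp), with Cd47 at 0.73, Cd44 at 0.69, the water channel Aqp1 at -0.73 and the erythropoietin receptor Epor at -0.59. Over whole genes from day 0 to day 1, the relative occupancy of every gene in the erythroid transcription factor list rose. The rise was smallest at Ldb1, from 4.42 to 5.43, and largest at Bcl11a, from 1.71 to 3.72. In that setting the median log2 change of all genes was 0.20, with 9649 of 14343 genes above 0.

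The progenitor, cell cycle, nuclear condensation and ribosomal protein lists also lay within the random range from day 0 to day 2. The 17 progenitor genes lay 0.27 below all genes (percentile 5.11; 0.21 above over whole genes), with Kit, the stem cell factor receptor, at -1.61, Spi1 at -0.86, Lyl1 at 0.30 and Fli1 at 1.29. The 28 cell cycle genes lay 0.09 above (percentile 77.7; -0.03 in windows of 1000 bp), with the helicase subunit Mcm6 at 1.71, Bub1 at 1.37, the replication clamp Pcna at -1.33 and Ccnd1 at -1.27. The 24 genes of nuclear condensation and enucleation had the median of all genes to 2 decimals (percentile 56.7), with Bnip3l at 0.69, Top2b at 0.66, Top2a at -1.15 and Cit at -0.88. The 82 members of the ribosomal protein list lay 0.13 below (percentile 9.10), with Rps20 at 1.44, Rps23rg1 at 1.06, Rpl23a at -0.98 and Rpl19 at -0.97. The symbol rule of this list also took genes that do not encode ribosomal proteins, among them Rps6k kinases and Rps23rg1.

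Markers of other cells that a fetal liver culture could hold were measured in the same way. From day 0 to day 2 the medians relative to all genes were 0.26 for 7 hepatocyte genes (percentile 84.5), -0.35 for 9 macrophage genes (5.66), 0.11 for 12 lymphoid genes (71.6) and 0.18 for 9 megakaryocyte genes (82.5). In windows of 1000 bp the hepatocyte, macrophage and lymphoid medians turned to -0.12 (19.04), 0.21 (78.4) and -0.14 (17.1), and over whole genes the medians of the 4 lists, in the first order, were -0.11, 0.48 (98.8), -0.16 and -0.16, so no direction is settled for these lists. The 8 neural genes lay at -0.15 (27.1). Examples were Hnf4a at 1.11 and Ahsg at -0.78, C1qc at -1.04 and Cd68 at -0.85, Cd3e at 1.26 and Rag2 at -0.82, Pf4 at 0.99 and Gp9 at -0.75, and Neurog2 at -1.58 and Tubb3 at 0.28. None of the 9 macrophage genes had a log2 change above 0, and the highest was Itgam at -0.007.

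From day 0 to day 1, ribosomal protein genes lay 0.21 above all genes, at percentile 99.4, with 55 of 82 members above the median of all genes. The rule for this list also took genes that its name does not describe, such as Rps6k kinases, and without such members 74 genes remained, at percentile 98.8. The 9 macrophage genes lay 0.73 below all genes (percentile 0.63), and Csf1r, a growth factor receptor, had a log2 change of -1.20, where the median of all genes was 0.45. The minimum of 3 positions left out 6 of the 15 members, among them Mpeg1 with a relative occupancy of 0.318 and 3.93 on days 0 and 1 and C1qa with 0.636 and 3.61. Over all 15 the median relative occupancy was 1.43 and 1.72. This was a smaller rise than that of the median over all genes, from 1.81 to 2.41. The size of the difference thus depends on the minimum, and the 9 do not stand for the list. With windows of 1000 bp the macrophage difference was 0.03 above, and over whole genes 0.02 above. From day 1 to day 2 the 24 genes of nuclear condensation and enucleation lay 0.18 above all genes (percentile 98.1), and -0.01 with windows of 1000 bp and -0.11 over whole genes. Over the 3 comparisons, 5 of 42 list medians lay outside the central 95% of random lists, where chance gives 2.1. In the narrower window from 200 bp outside to 50 bp inside each end, 0 did, and the histone list lay at percentile 84.9 and the ribosomal protein list at 73.9. In windows of 1000 bp 6 did, in part other lists: histone genes from day 0 to 1 (above all random lists) and day 0 to 2 (99.9), ribosomal protein genes (98.97) and lymphoid genes (0.89) from day 0 to 1, and olfactory receptor genes from day 1 to 2 (0.05) and day 0 to 2. Over whole genes 9 did. The random lists were not matched on gene length, with which the whole-gene change went. Its Spearman correlation with length was -0.44 from day 0 to 1, 0.60 from day 1 to 2 and 0.24 from day 0 to 2. Percentiles over whole genes may thus in part reflect gene length.

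**Figure D3:**
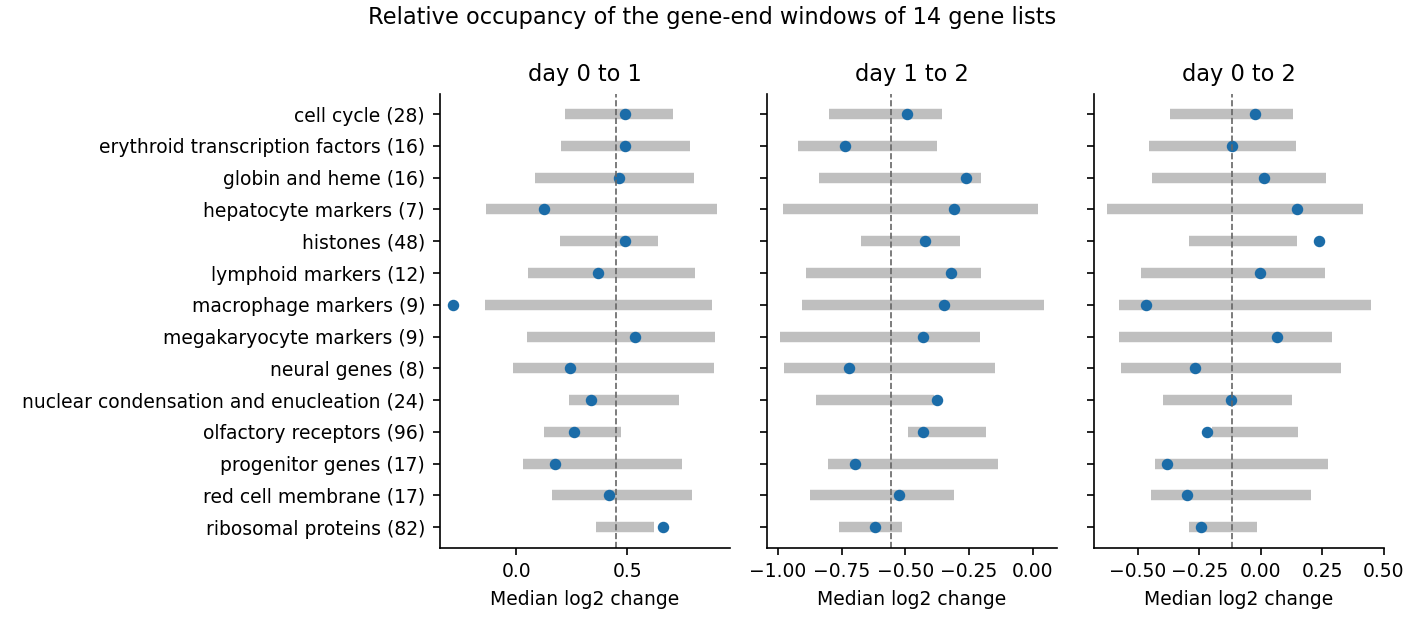
Dots show the median log2 change of relative occupancy of 14 gene lists in each comparison, with the number of measured members in parentheses, grey bars the central 95% of 10000 random lists matched on occupancy, and dashed lines the median of all genes. The histone median from day 0 to 2 is 0.24 and the ribosomal protein median from day 0 to 1 is 0.66.

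By a size rule of 2 times in either direction, 596 genes were higher and 917 lower on day 2 than on day 0. This direction held with each position counted once (199 and 670). It turned with no minimum of positions (3547 and 1859), at a summit value of 10 or more (261 and 26) and narrowly in windows of 1000 bp (798 and 792). Of the named genes with the largest increases, Cnga3, a channel subunit of cone photoreceptors on chromosome 1 from 37218241 to 37263384, had 3, 3 and 12 positions and a log2 change of 2.19, and its ratio of position numbers, divided by the ratio of the autosome totals of the lists (1.19), was 3.37 (exact 95% interval 0.909 to 18.6, counting error only), which includes 1. The other named increases were Ptger4, Zfp988, Traf6, Cnot1, Rassf8, Ranbp6, Tmbim4, Tifa and Enpep, with log2 changes down to 1.91. The largest decrease was at Msln, which encodes the surface protein mesothelin, on chromosome 17 from 25748613 to 25754378, with 12, 7 and 3 positions, a log2 change of -3.03 and a scaled ratio of position numbers of 0.210 (0.038 to 0.780). Lcn6 followed with -2.88, then Cacna1h, Pla2g2f, Fam217a, Nedd9, Mrgprd, Zbtb8b, Alpi and Lrrn2, up to -2.22. The counting interval of the scaled ratio excluded 1 for 0 of the 10 increases and 5 of the 10 decreases. Unscaled, it did so for 1 increase, Cnga3 (4, 1.08 to 22.1), and 2 decreases, Msln and Lcn6, so this split depends on the scaling. The 20 named genes were picked as the extremes of 14093, so the intervals do not test them, and 18 of the 20 had the minimum of 3 positions on at least 1 day. Among genes with positions at both ends, the changes at the 2 ends of a gene had a Pearson correlation across genes of 0.015 for day 0 to 2 (Spearman 0.027).

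From day 0 to day 1, 2288 genes were higher and 183 lower, and from day 1 to day 2, 84 and 2787. Scaling each library to the median of its own gene windows, which brings the median change near 0 by construction and so cannot show where the split comes from, gave 766 and 685, then 423 and 743, and 625 and 877 from day 0 to day 2. Relative to the median of all genes, Tm9sf3 (2.45), Kalrn (2.19) and Ypel4 (2.17) had the largest log2 increases from day 0 to 1, and Lcn6 (-2.64), Clec4f (-2.60) and Chrna4 (-2.55) the largest decreases. From day 1 to 2 these were Cnga3 (2.48), Ly6c2 (2.44) and Itgb2l (2.29), and Purb (-2.42), Sdk1 (-2.14) and Grap (-2.04). Over whole genes instead of their ends, the median log2 change kept its sign, at 0.20, -0.35 and -0.17 from day 0 to 1, 1 to 2 and 0 to 2, with 9649, 3898 and 4828 of 14343 genes above 0. The genes past 2 times went the other way, with 146 higher and 524 lower from day 0 to 1, 702 and 223 from day 1 to 2, and 429 and 160 from day 0 to 2.

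Nucleosome positions of different days lay at weakly regular distances from each other. Of the day 0 positions, 13.6% had a day 1 centre within 20 bp, against 10.4% after a shift of 1000 bp, a ratio of 1.30 ± 0.037 (SD over 19 autosomes). From day 1 to day 2 the shares were 18.4% and 13.7% (ratio 1.34 ± 0.029), and from day 0 to day 2, 15.7% and 12.1% (1.30 ± 0.022). Most coincidences were thus also found with a shifted list. Distances between the lists of 2 days had maxima 192 bp apart for days 0 and 1 (range 191 to 193 bp when each chromosome was left out in turn), 196 bp for days 1 and 2 (187 to 198 bp) and 189 bp for days 0 and 2 (187 to 191 bp). The line for days 0 and 2 went through 4 maxima from 577 bp on, without the one at 373 bp that the other 2 had among their 5, so the 3 slopes are not fully alike.

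Within a list, the slope through all maxima up to 1000 bp was 166 bp on day 0, 202 bp on day 1 and 165 bp on day 2. The first of these maxima, at 145, 134 and 142 bp, lie next to the minimum distance of 100 bp between listed centres, and the day 1 list had 5 maxima where the others had 6. With maxima from 300 bp on, the spacing was 184 bp (183 to 186 bp), 188 bp (188 to 198 bp) and 188 bp (188 to 189 bp). The day 0 maxima after 403 bp were barely raised. Relative to the mean from 1000 to 1400 bp, pair numbers there were 1.0051, 1.0055, 1.0044 and 1.0043. At 640 bp, which is no maximum, the number was 1.0111. The maxima at 553 bp on day 1 and 563 bp on day 2 stood at 1.0364 and 1.0183. The ranges only show the effect of leaving out chromosomes, so the day 0 spacing is less certain than its range. The most frequent distance between neighbours was 140 to 149 bp on day 0, 120 to 129 bp on day 1 and 130 to 139 bp on day 2.

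**Figure D4:**
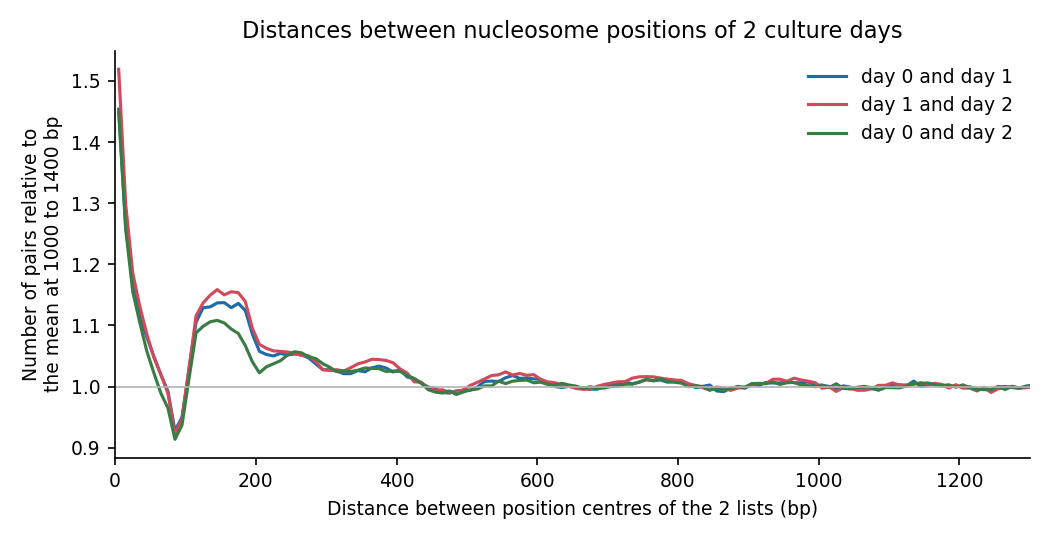
Lines show the number of pairs of position centres, 1 from each of 2 culture days, against their distance in bp, relative to the mean number from 1000 to 1400 bp. The maxima lie 192 bp apart for days 0 and 1, 196 bp for days 1 and 2 and 189 bp for days 0 and 2.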

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

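All tests of explanations in this part were chosen after the patterns were seen. Positions were listed on chromosomes outside the comparisons: 16, 5 and 89 on the mitochondrial genome on days 0, 1 and 2, and 1127, 975 and 3396 on chromosome Y. The sex of the fetuses is not given in the sources used here, which limits what the chromosome Y numbers mean.

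The first pattern is the larger share of day 2 signal in gene-poor bins. If the share followed depth, day 2 would lie between the other days, so depth alone is argued against, as the inferred depth of day 2 lies between those of the other days while its share lies above both, 1.99 ± 0.30 times the higher of them and above 1 on all 19 autosomes. Whether the summit value needed for listing contributes is not settled. Among positions with a summit value of 12 or more, these bins held only 1449 on day 0 and 1159 on day 2. There the ratio of day 2 to day 0 was 2.23 ± 1.82, between 1.00 and 8.93 and above 1 on all 19 autosomes. With so wide a spread this ratio decides neither way. At a summit value of 10 or more, a second threshold tried after the first was seen, the ratio was 2.48 ± 0.93, also above 1 on all 19 autosomes. The choice between these thresholds is not settled. Digestion or base composition cannot be told apart from the day with 1 library each, the correlation of the change with gene density, -0.59, restates the pattern and decides nothing, and a biological difference between culture days stays open and untested.

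The second pattern is the higher fuzziness score of day 1, with a median of 54.5 against 51.0 on both other days. The number of reads per position is unlikely to be its whole cause, since at 16 steps of summit value day 1 was still higher by 2.55 ± 0.22 (SD over 19 autosomes). This number of steps is below the day 1 median of 21 and above the median of 10 on days 0 and 2. It thus sets weaker positions of day 1 against stronger ones of the other days. At 24 steps the median scores were 50.2, 54.6 and 50.3 on days 0, 1 and 2, so the size of the difference depends on the step chosen. Positions near the summit value needed for listing are likewise argued against, since at summit values from 10 to 12 the difference was 3.78 ± 0.20. The joint action of both was not tested, and digestion of the day 1 sample and the culture day stay open as untested explanations.

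The third pattern is the stronger gene-end profile of day 1. Depth may account for it: among the 1000000 positions with the highest summit values of each list, the inside to outside ratio was 1.24, 1.43 and 1.30 on days 0, 1 and 2, which leaves day 1 at 1.10 times the higher of the others. The order of the 3 days over all positions is also the order of their inferred depth, so depth and day cannot be told apart here, and the culture day stays open.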

How the results depend on the processing

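The settings with whole genes, without members with overlapping windows, a summit value of 10 or 12, maxima from 300 bp on and 10 density classes with ties broken were chosen after the data were seen. The profile around motif sites was not run, and no paired test is given. No paired analysis was possible because there is 1 library per day and no result comes from a test. The cause of each difference below was not tested, except that fewer positions follow from leaving some out. The number of positions per window limits single genes.

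Without positions at or below the 25% quantile of summit values, where many values are tied, there were 2190121, 1957504 and 2934585 positions on days 0, 1 and 2, with 41.4%, 34.7% and 34.4% left out. The spacing slope then was 217.5, 203.4 and 212.7 bp, and in the 25% with the lowest fuzziness score 231.5, 182.4 and 183.9 bp. With maxima from 300 to 1200 bp it was 184, 188 and 188 bp, and to 1400 bp 186, 187 and 173 bp. Between lists, the range to 1400 bp gave 195.2 bp for days 0 and 1 and 194 bp for days 0 and 2. The ratio of shared to shifted positions stayed above 1 in each setting run, in the order day 0 to 1, 1 to 2 and 0 to 2: 1.37, 1.43 and 1.37 within 10 bp, 1.22, 1.24 and 1.21 within 40 bp, and 1.38, 1.42 and 1.38 above the 25% summit quantile.

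At gene ends, the inside to outside ratio on days 0, 1 and 2 was 1.11, 1.18 and 1.11 with each position counted once, 1.202, 1.40 and 1.2035 above the 25% summit quantile, and 1.34, 1.92 and 1.43 at a summit value of 10 or more. The first maximum was 1.34 and 1.24 high on days 1 and 2 counted once, and 1.49, 2.24 and 1.72 on days 0, 1 and 2 at 10 or more, where the trough was 0.744 on day 0 and 0.806 on day 2. At 10 or more this maximum lay 105, 135 and 105 bp from the end, so its place on day 1 moved further than 1 step.

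Genes at least 2 times higher and lower from day 0 to 1 numbered 1167 and 117 counted once, 4095 and 2104 with no minimum, 766 and 685 scaled to the gene median, 571 and 8 at a summit value of 10 or more and 146 and 524 over whole genes, with 482 lower in windows of 1000 bp. From day 1 to 2 they numbered 315 and 1806 in windows of 1000 bp, 43 and 1856 counted once, 423 and 743 scaled to the gene median, 37 and 281 at 10 or more and 702 and 223 over whole genes, with 45 higher above the 25% summit quantile and 2975 higher with no minimum. From day 0 to 2, 199 were higher counted once, 355 above the 25% summit quantile, 3547 higher and 1859 lower with no minimum, 261 and 26 at 10 or more, and 160 lower over whole genes. Among genes past 2 times, the direction of the split thus turned for all 3 comparisons over whole genes, though the median change kept its sign, and from day 0 to 2 also with no minimum, at 10 or more and in windows of 1000 bp (798 higher, 792 lower), where the median log2 change was 0, 0.33 and -0.11.

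In the trough window, 200 bp outside to 50 bp inside, 0 lists lay outside the central 95% of random lists from day 0 to 1, 0 from day 1 to 2 and 0 from day 0 to 2, and over whole genes 5 did from day 0 to 1. The macrophage difference from day 0 to 1 turned to 0.031 in windows of 1000 bp and 0.023 over whole genes, and that of nuclear condensation and enucleation from day 1 to 2 to -0.0074 and -0.11. In the gene-poorest bins, the day 1 to day 0 ratio turned to 1.10 ± 0.94 at a summit value of 12 or more, where day 2 to day 1 was 2.02, and 0.808 in the gene-richest. The day 2 to day 0 ratio was 2.48 at 10 or more, and with ties broken into 10 density classes 2.60, with 3.23 for day 2 to day 1.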

Other observations

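The whole-gene values and the olfactory window counts in this part were chosen after the data were seen. Most very long genes had a higher occupancy on day 2 than on day 0. Of 226 genes of 500 kb or more, 177 had a higher and 49 a lower relative occupancy over the whole gene on day 2 than on day 0, with a median log2 change of 0.72, after -0.63 from day 0 to 1 and 1.40 from day 1 to 2. The gene-poorest bins went the same way, with ratios of 0.771 from day 0 to 1, 2.58 from day 1 to 2 and 1.99 from day 0 to 2. How far long genes lie in these bins was not measured, so this may be the same pattern. The largest log2 increases over whole genes of any length, with at least 20 positions on each day and without predicted or clone-named gene models or genes with an end within 5 kb of an end of one already listed, were at Cdh18 (2.88, on chromosome 15 from 22548898 to 23477491) with 79, 173 and 652 positions, Plcxd3 (2.70), Slc22a27 (2.69), Cdh12 (2.47) and Cdh10 (2.45). The largest decreases were at Arhgef16 (-1.78), Msln (-1.59), Trp73 (-1.51), Nkx2-5 (-1.50) and Lrrn2 (-1.48).

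Olfactory receptor genes, which lie in clusters, often had no listed position at either end. This was so for 543 of 1109 genes on day 0 (49.0%, exact 95% interval 46.0 to 52.0%), 532 on day 1 (48.0%, 45.0 to 51.0%) and 202 on day 2 (18.2%, 15.98 to 20.6%). Among the other 20414 genes the shares were 8.89%, 10.6% and 3.68%.

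Across all 21523 genes, which are not independent replicates, the Spearman correlation of relative occupancy was 0.82 between days 0 and 1, 0.83 between days 1 and 2 and 0.78 between days 0 and 2. Among the genes with at least 3 positions on each day it was 0.63, 0.66 and 0.56. For the changes at the 2 ends of a gene, the Pearson correlation was -0.06 from day 0 to 1 and -0.02 from day 1 to 2.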
